A study of Mus musculus with 20 samples.

How the data were processed

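The study sequenced total RNA of CD31-positive cells that were enriched with microbeads and sorted from E0771 tumours, per the labels' protocols. The RNA was amplified with the MATQ method and made into libraries with a Nextera XT kit, which does not mark strand, so reads of a gene and of an antisense partner cannot be told apart. Per the submitters' processing notes, the tools were bcl2fastq 2.17, STAR (version not given in the sources used here), RSEM 1.2.28 and DESeq2, with the mouse build GRCm38. The annotation release is not given in the sources used here.

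For each of the 20 libraries the authors deposited 1 table with an expected count, a TPM value and an effective length for each of 46983 gene IDs. The expected counts are RSEM's estimated counts, not normalized, per the file headers. The TPM values, deposited by the authors, are scaled for length and depth and were only looked at, not tested. The effective length, also deposited, is another quantity of RSEM per gene and library, and served only in an alternative. Of the expected counts 4.45% were not whole numbers, and all were rounded to whole numbers first. A GRCm38 annotation gave a symbol and a position for 46488 IDs; the other 495 IDs stayed in the counts under their ID, with 0.00685% to 0.0899% of a library's counts, and 59 symbols stood on more than 1 ID. RSEM shares reads between near-identical genes, so single members of such families are uncertain.

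Groups were taken from the labels: 6 backgrounds, and the submitters' division into CD4-competent and CD4-deficient. The 8 comparisons, their tests, the gene lists and the rule for named genes were fixed before the data were examined. Nothing pairs libraries across backgrounds, since each library number is used once.

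The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust estimation, TMM factors and filterByExpr by group, which kept 14875 genes. Adjusted p-values are Benjamini-Hochberg values over these genes with a threshold of 0.05. The comparison by CD4 status used a 2-group model, and the others a 6-group model in which all backgrounds share 1 estimate of the spread. Changes are log2 fold changes with a standard error obtained from the F statistic. CPM values use the effective library sizes. The common biological coefficient of variation was 0.995 in the 6-group model and 1.08 in the 2-group model, and TMM factors ran from 0.523 to 3.69.

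Of 37 gene lists with 567 genes in all (2 symbols, Ca9 and Ahsp, had no match), 31 had at least 5 tested genes and were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over lists within a comparison. Camera with an estimated correlation and fry were run beside it. With the estimated correlation 0 lists passed in any of the 8 comparisons, and fry passed lists in TCRKO against WT only. Counts "adjusted over the list alone" use edgeR p-values adjusted within a list.

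Genes are named by rule. In every library these are Cd4, Cd8a, Cd8b1, Trac, Trbc1, Trbc2, H2-Ab1, Cd3e and Pecam1. In each comparison they are up to 10 genes per direction past the threshold with a mean of at least 10 CPM, filled up to 5 per direction by the smallest p and then given as values only. In each list described they are the 4 members with the smallest p and a mean of at least 1 CPM. The text gives part of them, and no fitted fold where a group held 3 counts or fewer in all; a ratio of summed counts with an exact Poisson interval (95%) stands in its place.

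The scripts were tested on simulated data with 200 changed genes per comparison. At 16-fold between 74% (the difference of effects) and 100% (CD4 status) were recovered. At 4-fold the share was 89% for CD4 status, 7% for the difference of effects and 24% to 27% for the others. A list shifted by 1 on the log2 scale was called in 6 of the 8 comparisons, not in CD4KO against WT or the difference of effects. Apart from these changes all simulated libraries shared the same mean per gene, and genes varied independently. Only genes with at least 10 CPM were changed. The simulation thus held no differences between backgrounds and no satellite-rich libraries, so these shares may overstate the power, above all for CD4 status.

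Alternatives were DESeq2 1.42.0, limma-voom with sample weights, RLE factors, no filter, a filter of 5 CPM in 10 libraries, effective-length offsets, only the groups compared, only the nearest WT library numbers, a library-number covariate, background means, and leaving out each library in turn. Added after the data were seen were the removal of the 2 satellite-rich libraries, the removal of ribosomal, mitochondrial and other abundant RNA and satellite genes, and the share of olfactory receptor counts as a covariate. Replicate libraries were compared by chi-square over genes, and each pair differed by far more than sampling noise (17.9 to 627 per degree of freedom), so none was counted as a duplicate. This check can find copied libraries only, not separate libraries made from the same animal. Figures and summaries used Python 3.11.15.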

Results

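Bulk RNA sequencing was done on CD31-positive cells sorted from orthotopic E0771 tumours. E0771 is a mouse mammary carcinoma line grown here in the mammary fat pad of C57BL/6J hosts, and CD31 (Pecam1) is a surface protein of endothelial cells. The 20 libraries came from 6 host backgrounds. The submitters class 3 of these as competent for CD4 T cells: wild type (WT, n = 4), CD8KO (n = 3) and Tie2Cre (n = 3). The other 3 are classed as deficient: CD4KO (n = 3), TCRKO (n = 3) and Tie2Cre_H2Abf (n = 4), in which a floxed H2-Ab1 allele is combined with Tie2Cre, a Cre recombinase active in endothelial and blood cells. Libraries are named by background and the number in their label; such a name gives the label only. Nothing in the labels says that each library came from a separate animal, so p-values measure only the spread between these samples.

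Total counts ran from 1543850 in Tie2Cre_9501 to 11478900 in Tie2Cre_H2Abf_9589, with a median of 7531925. Ribosomal-RNA-like and other abundant RNA genes, such as CT010467.1 and 7SK RNA, took 17.2% of the counts in CD8KO_9752 and 86.9% in WT_9749, with a median of 75.3%. Protein-coding genes held 12.8% in WT_9749 and 81.0% in CD8KO_9752, with a median of 24.2%. Satellite-like genes took 45.9% of the counts in WT_9771 and 19.3% in Tie2Cre_9501, and these 2 libraries are called satellite-rich. The classes overlap: in WT_9771 abundant RNA took 41.3% and protein-coding genes 51.2%, which with the satellite share exceeds its total count. Protein-coding counts thus include satellite-like genes. Olfactory receptor shares of protein-coding counts, also used as a covariate, are therefore too low in the satellite-rich libraries. Between 11914 genes (WT_9748) and 21358 genes (Tie2Cre_9501) had a count. A floor of 3 counts corresponded to 0.128 CPM in CD8KO_9752 and 2.46 CPM in WT_9771; such floors and intervals cover counting error only. Libraries of one background had a median Spearman correlation of 0.777, and libraries of different backgrounds 0.765. The first principal component held 38.6% of the variance, with WT_9771 and Tie2Cre_9501 at its far end.

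**Figure D1:**
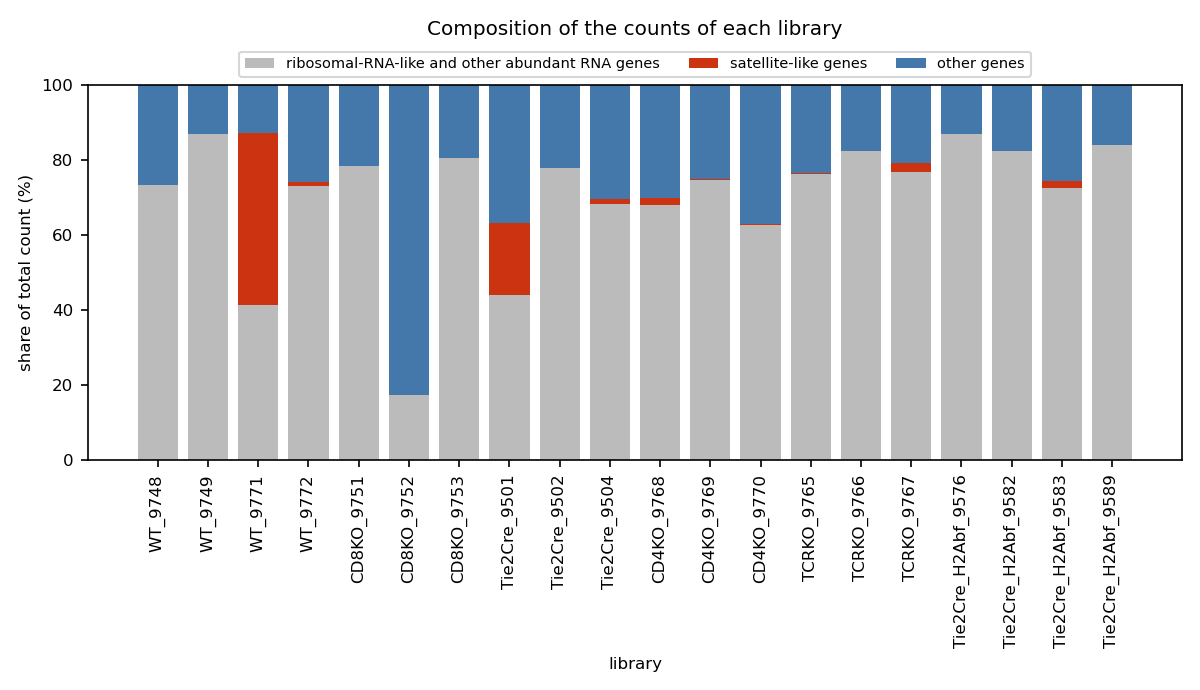
Share of each library's total count (%, vertical axis) taken by ribosomal-RNA-like and other abundant RNA genes, satellite-like genes and other genes, 1 bar per library ordered by background. The satellite share reached 45.9% in WT_9771 and 19.3% in Tie2Cre_9501.

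The genes altered in the hosts were read in every library first. H2-Ab1, the beta chain of the I-A class II molecule, stood at 6.37, 1.19, 0.712 and 4.34 CPM in the 4 Tie2Cre_H2Abf libraries, against 60.5 ± 35.4 CPM in Tie2Cre (SD, n = 3) and 115 ± 57.2 CPM in WT (SD, n = 4). Cd8a, the alpha chain of CD8, stood at 48.7, 39.0 and 69.8 CPM in the 3 libraries labelled CD8KO. In the other 17 libraries it reached at most 2.94 CPM. WT held 3 Cd8a counts in all, so a loss of Cd8a could not have been seen in this sort. Its RNA marks the 3 libraries labelled CD8KO but does not decide their label. Cd8b1, the CD8 beta chain, had 0 counts in these 3 libraries and at most 0.756 CPM elsewhere. Cd4 RNA was present in the 3 libraries labelled CD4KO, with 72, 33 and 102 counts (15.7, 4.22 and 7.55 CPM), all above the floor, against 0.379 to 15.6 CPM in WT. Cd4 RNA could not test this label. T cell genes were near the floor in all backgrounds, so a loss of Cd4 in T cells could not have been seen. The highest CD4KO and WT values came from CD4KO_9768 and WT_9771, libraries with large olfactory receptor shares (2429 and 2766 CPM of protein-coding counts). The source of the Cd4 counts was not tested. Trac, Trbc1 and Trbc2, the constant regions of the T cell receptor chains, reached at most 1.78 CPM in any library, and Cd3e at most 1.96 CPM. At these levels a loss of the receptor chains was not detectable. In what follows the 3 libraries are written as labelled CD8KO, and every comparison with them depends on that label. Pecam1 was high throughout, from 435 CPM in WT_9771 to 1377 CPM in Tie2Cre_9502.

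**Figure D2:**
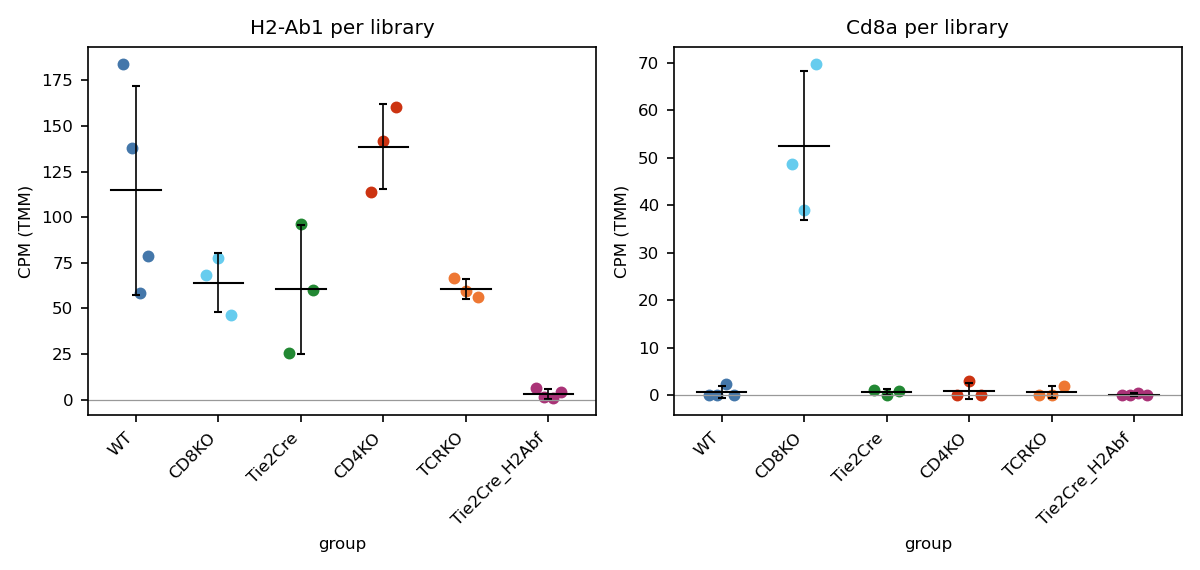
H2-Ab1 and Cd8a in CPM (vertical axes, linear) by background, 1 point per library, with the group mean and SD. H2-Ab1 lay at or below 6.37 CPM in the 4 Tie2Cre_H2Abf libraries, and Cd8a at or above 39.0 CPM in the 3 libraries labelled CD8KO.

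The series divides the hosts by CD4 status, and the first comparison set the 10 deficient against the 10 competent libraries. Genes of endothelial tip cells, the leading cells of vessel sprouts, were higher in deficient hosts as a group (mean log2 change 0.52, 16 of 18 members higher; camera adjusted p = 0.00706, adjusted p = 0.825 with an estimated correlation). Examples were Apln, a secreted ligand of the apelin receptor (1.17 ± 0.37, SE), Pgf, a growth factor of the VEGF family (1.08 ± 0.42), and Igfbp3 (0.74 ± 0.34). Genes of venous endothelium were lower as a group (mean -0.52, 6 of 8 lower; camera adjusted p = 0.0145, adjusted p = 0.825 with an estimated correlation), among them Il6st, the shared receptor subunit of interleukin 6 signalling (-0.92 ± 0.28), and Selp, the adhesion molecule P-selectin (-1.08 ± 0.35). Adjusted over the list alone, these last 2 venous genes passed, and 0 tip cell genes did. The backgrounds did not move alike, although this model takes their libraries as replicates. The tip cell score (mean log2 CPM) was 5.27 ± 0.65 in CD4KO, 6.08 ± 0.34 in TCRKO and 6.36 ± 0.17 in Tie2Cre_H2Abf, against 5.45 ± 0.72 in WT, 5.94 ± 0.19 in CD8KO and 4.91 ± 0.84 in Tie2Cre (SD), so CD4KO lay below WT. The venous score was low in TCRKO only (4.81 ± 0.35), at 6.41 ± 0.30 in CD4KO and 6.13 ± 0.21 in Tie2Cre_H2Abf against 6.15 ± 0.45 in WT, 6.35 ± 0.45 in CD8KO and 6.56 ± 0.34 in Tie2Cre.

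No single gene passed in that comparison: edgeR called 0 of 14875 genes, with 1081 under an unadjusted p of 0.05 where 744 are expected by chance, DESeq2 called 11 and limma-voom 8. Of 100 splits of these libraries, the real one included, 21 gave at least 1081 such genes, so the excess over 744 cannot be credited to CD4 status. Among genes eligible for naming, with a mean of at least 10 CPM, Fbln2, an extracellular matrix protein, had the smallest p (-1.42 ± 0.35). Hspb8 (2.07 ± 0.52) and Cdk6 (1.14 ± 0.29) came next, and none of the 3 passed the threshold (edgeR adjusted p = 0.375 for each). Vegfa, the main angiogenic growth factor, had a fitted change of 4.03 ± 1.01 (edgeR adjusted p = 0.375, and 0.00458 adjusted over the list alone), but stood at 17.1 CPM or less in every library. The tip cell call ended without Tie2Cre_9501 or WT_9771 (adjusted p up to 0.122), both satellite-rich, and without both the mean was 0.20 (adjusted p = 0.490). The venous call ended without CD8KO_9751, CD8KO_9752, Tie2Cre_9502 or any of the 3 TCRKO libraries (adjusted p up to 0.135).

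CD4KO against WT compares hosts labelled as lacking CD4 alone with WT. It rests on that label, which Cd4 RNA, present in all 3 CD4KO libraries, could not test. Ribosomal protein genes were higher in CD4KO (mean 0.68, 28 of 28 members higher; camera adjusted p = 0.00450, adjusted p = 0.948 with an estimated correlation), with Rplp1 at 1.48 ± 0.59. Fibroblast genes were also higher as a group (mean 1.12, 11 of 14; camera adjusted p = 0.0405, adjusted p = 0.948 with an estimated correlation), led by Col6a2, a collagen VI chain with 139 counts in CD4KO and 2 in WT (ratio 46.3, exact Poisson interval 12.6 to 386), and Mmp2, a matrix protease (2.31 ± 0.87). The interferon-gamma response, MHC class II and venous lists did not pass, at means of 0.45, 0.12 and 0.25. Adjusted over the list alone, 1 fibroblast gene (Col6a2) and 0 ribosomal protein genes passed.

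At single genes edgeR called 0 in CD4KO against WT, with 1277 under an unadjusted p of 0.05, and DESeq2 called 94. The following ranking covers genes eligible for naming, with a mean of at least 10 CPM. The lowest p values on the higher side were those of Kctd12 (3.13 ± 0.60, edgeR adjusted p = 0.161), Trp53inp2 (2.73 ± 0.58) and Trmt1 (2.67 ± 0.61). On the lower side it was that of Stam (-2.24 ± 0.65). The ribosomal call ended without CD4KO_9768, WT_9748 or WT_9771 (mean down to 0.26, adjusted p up to 0.512), and the fibroblast call without any 1 of 6 of the 7 libraries, WT_9771 being the exception (adjusted p up to 0.322).

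TCRKO against WT compares hosts labelled as lacking the T cell receptor with WT; it rests on that label, as Trac had 5, 9 and 3 counts in TCRKO and 0, 0, 1 and 0 in WT. Venous genes fell (mean -1.35, 7 of 8 members lower; camera adjusted p = 6.18e-06, adjusted p = 0.0717 with an estimated correlation): Il6st -1.82 ± 0.37, Selp -2.26 ± 0.52, Vwf, the von Willebrand factor, -2.0 ± 0.50, and Vcam1 -1.95 ± 0.54. Leukocyte adhesion molecules fell with them (mean -0.97, 10 of 14; camera adjusted p = 0.000320, adjusted p = 0.0717 with an estimated correlation), including Cx3cl1 (-2.09 ± 0.61). Sele, E-selectin, had 1 count in all 3 TCRKO libraries and 204 in WT, a ratio of 0.00404 with an exact Poisson interval (95%, counting error only) from 0.000102 to 0.0228; the WT libraries ranged from 0 counts (WT_9771) to 102 (WT_9772). Selp and Vcam1 are on both lists.

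Genes of MHC class II and of the interferon-gamma response were also lower in TCRKO; the lists for MHC class I (mean -0.30, camera adjusted p = 0.129) and the type I interferon response (mean 0.17, camera adjusted p = 0.936) did not pass. The interferon-gamma response list fell (mean -0.84, 27 of 29 members lower; camera adjusted p = 5.23e-08, adjusted p = 0.188 with an estimated correlation), with the guanylate-binding proteins Gbp2 (-1.94 ± 0.40) and Gbp4 (-1.37 ± 0.40), and Wars, an interferon-induced tRNA synthetase (-1.76 ± 0.46). The MHC class II list fell (mean -1.44, 7 of 8; camera adjusted p = 0.000174, adjusted p = 0.128 with an estimated correlation), with Cd74, the invariant chain, at -2.48 ± 0.56 and H2-Aa at -1.65 ± 0.53. The TNF and NF-kappaB list fell (mean -0.68, 10 of 18; camera adjusted p = 0.0106, adjusted p = 0.205 with an estimated correlation). Ribosomal protein genes rose (mean 1.40, 28 of 28; camera adjusted p = 8.12e-12, adjusted p = 0.419 with an estimated correlation), for example Rpl5 (2.18 ± 0.65). Adjusted over the list alone, 6 venous, 5 adhesion, 6 interferon-gamma, 6 MHC class II and 3 TNF genes were lower and 11 ribosomal genes higher, while over all 14875 genes none of these passed. The macrophage list did not pass (mean -0.18, camera adjusted p = 0.295), but without the 2 satellite-rich libraries, of which WT_9771 is in this comparison, it did (mean -0.35, camera adjusted p = 0.0402), as did endothelial identity (mean -0.35, camera adjusted p = 0.00223) and MHC class I (mean -0.46, camera adjusted p = 0.00242), all lower. That MHC class I did not pass with all libraries therefore depends on these libraries. Further lists passed in that setting and are not described here, so the lower lists named are not its whole result. Fry, which tests whether a list moves one way on balance, passed 4 of these lists: venous, adhesion, MHC class II and interferon-gamma.

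The edgeR test called 4 single genes in TCRKO against WT, all at an adjusted p of 0.0339, with 1286 under an unadjusted p of 0.05; DESeq2 called 177, the same 4 among them, and limma-voom 5, with 1 of the 4 among them. Effective-length offsets kept 2 of the 4, and the fits of only the 2 groups and of only the nearest WT library numbers called 0 genes. Fbn1, fibrillin-1 of extracellular microfibrils (chromosome 2, 125300594 to 125507993, GRCm38), fell by 4.34 ± 0.78 on the log2 scale, to 1.38 ± 0.787 CPM (SD, n = 3) from 28.6 ± 15.7 CPM in WT (SD, n = 4). Trp53inp2, an autophagy regulator (chromosome 2, 155381059 to 155389850), rose by 3.26 ± 0.59, from 2.88 ± 2.74 to 30.0 ± 4.0 CPM. Col6a2 rose from 2 counts in all 4 WT libraries to 354 in the 3 TCRKO libraries, to 17.5 ± 4.69 CPM (SD, n = 3), a ratio of 146 with an exact Poisson interval from 40.1 to 1209. Neither rise was particular to TCRKO. Against WT, Trp53inp2 also had estimates of 2.73 in CD4KO, 2.94 in the libraries labelled CD8KO and 2.77 in Tie2Cre. Over the same WT counts Col6a2 had ratios of 46.3 in CD4KO and 28.5 in the libraries labelled CD8KO. Cadm3, an adhesion molecule named here after its values were seen, fell by 4.65 ± 0.84. Among genes that did not pass were Col15a1, a basement membrane collagen (-2.23 ± 0.43, edgeR adjusted p = 0.0621), Apln (2.22 ± 0.46, adjusted p = 0.104) and Angptl2 (3.81 ± 0.83, adjusted p = 0.121).

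Without TCRKO_9765, TCRKO_9766 or TCRKO_9767, or without WT_9748, 0 genes passed, without WT_9749 2, without WT_9771 10 and without WT_9772 18; each of the 4 genes was lost in 4 or 5 of these 7 fits. Of the 6 lists, 5 passed in all 7 fits, and the TNF list ended without TCRKO_9767, WT_9748 or WT_9749 (adjusted p up to 0.170). Without the 2 satellite-rich libraries, a setting chosen after the data were seen, 15 genes passed, the 4 called ones included, and Il6st (-1.90 ± 0.32), Selp (-2.50 ± 0.43), Cd74 (-2.67 ± 0.49), Gbp2 (-1.89 ± 0.37), Vwf (-2.21 ± 0.43), Col15a1 (-2.38 ± 0.37) and Fbln2 (-2.06 ± 0.38) were among the others.

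The 3 libraries labelled CD8KO were set against WT as another competent background, with the label taken as given, since Cd8a RNA does not decide it. MHC class II genes were lower as a group (mean -1.11, 8 of 8 members lower; camera adjusted p = 0.00286, adjusted p = 0.479 with an estimated correlation), with Cd74 at -2.19 ± 0.55 and H2-DMb1 at -1.99 ± 0.74. The interferon-gamma response list was lower (mean -0.47, 23 of 29; camera adjusted p = 0.00218, adjusted p = 0.653 with an estimated correlation), with Gbp5 at -1.53 ± 0.49 and the chemokine Cxcl9 at -1.28 ± 0.53. Macrophage genes were lower (mean -0.45, 14 of 18; camera adjusted p = 0.0469, adjusted p = 0.790 with an estimated correlation), including the receptor Csf1r (-1.78 ± 0.72) and the complement gene C1qc (-1.46 ± 0.60). Ribosomal protein (mean 0.80, 28 of 28; adjusted p = 0.000140), endothelial identity (mean 0.59, 22 of 23; adjusted p = 0.0125) and fibroblast genes (mean 1.15, 11 of 14; adjusted p = 0.0175) were higher by camera, at adjusted p = 0.790, 0.790 and 0.479 with an estimated correlation. Plvap, a protein of fenestrated endothelium (1.57 ± 0.52), led the identity list. Adjusted over the list alone, 2 MHC class II genes were lower and 2 fibroblast genes, Col6a2 and Mmp2, higher.

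In the libraries labelled CD8KO edgeR called 0 genes against WT, with 1568 under an unadjusted p of 0.05, and DESeq2 called 82 and limma-voom 1. Cd8a itself, higher in the libraries labelled as its knockout, had 1853 counts against 3 in WT (ratio 273, exact Poisson interval 93.4 to 1327) without passing (edgeR adjusted p = 0.465), and Trp53inp2 (2.94 ± 0.58) and Tlnrd1 (3.19 ± 0.68) had the smallest p. None of the 6 list calls held in all 7 fits that left out 1 library: without WT_9748 1 list passed, without WT_9749 2, and without CD8KO_9752 12. WT_9748 ended the MHC class II, interferon-gamma, ribosomal, fibroblast and macrophage calls, WT_9749 these but the ribosomal one, CD8KO_9751 the interferon-gamma and macrophage calls, CD8KO_9752 and CD8KO_9753 the macrophage call, and WT_9771 the endothelial identity call (mean 0.23, adjusted p = 0.564).

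Tie2Cre_H2Abf against Tie2Cre asks what happens when class II is removed from Tie2-lineage cells. H2-Ab1 (chromosome 17, 34257689 to 34269419, GRCm38) was 19.1-fold lower (-4.26 ± 0.59; edgeR adjusted p = 0.00214). Fbln2, fibulin-2 of the extracellular matrix (chromosome 6, 91212455 to 91272540), was 6.32-fold lower (-2.66 ± 0.41; edgeR adjusted p = 0.00670), at 78.7 ± 22.8 CPM (SD, n = 4) against 497 ± 162 CPM (SD, n = 3). Fabp4, a fatty-acid-binding protein of capillary endothelium (chromosome 3, 10204088 to 10208576), was 6.61-fold lower (-2.72 ± 0.49; edgeR adjusted p = 0.0401), at 28.8 ± 14.5 against 190 ± 29.9 CPM. Each of the 3 was lower in 4 of 4 Tie2Cre_H2Abf libraries than in any Tie2Cre library. They were the only genes edgeR called, with 1271 under an unadjusted p of 0.05. DESeq2 called 57 and limma-voom 15, the same 3 among each. Effective-length offsets and the olfactory covariate each kept 2 of the 3, and the fit of only the 2 groups kept 1. Fbln5 (-2.55 ± 0.50, edgeR adjusted p = 0.0977) and Fn1, fibronectin (2.41 ± 0.53, edgeR adjusted p = 0.217), did not pass.

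Tip cell genes were higher in Tie2Cre_H2Abf (mean 1.45, 17 of 18 members higher; camera adjusted p = 1.38e-08, adjusted p = 0.450 with an estimated correlation). Examples were Dll4, a Notch ligand of tip cells (1.57 ± 0.42), Apln (1.80 ± 0.49), Pgf (2.30 ± 0.68) and Igfbp3 (1.75 ± 0.55); adjusted over the list alone 11 were higher and 1 lower, and over all 14875 genes 0. The tip cell score (mean log2 CPM) was lowest in Tie2Cre_9501 (3.94), WT_9771 (4.39) and CD4KO_9768 (4.53), which also held the most olfactory receptor counts (5826, 2766 and 2429 CPM of protein-coding counts). The interferon-gamma response list was higher (mean 0.74, 24 of 29; camera adjusted p = 4.70e-05, adjusted p = 0.450 with an estimated correlation), with Cxcl9 at 1.84 ± 0.55 and Wars at 1.59 ± 0.45. Apart from H2-Ab1, the other tested MHC class II genes all had higher estimates (list mean 1.04, 7 of 8; camera adjusted p = 0.0140, adjusted p = 0.450 with an estimated correlation), such as H2-DMb1 (2.30 ± 0.75) and Cd74 (1.61 ± 0.54). The rise was over a low level in Tie2Cre: the MHC class II score was 4.37 ± 0.48 in Tie2Cre_H2Abf, 3.33 ± 0.63 in Tie2Cre and 4.73 ± 0.67 in WT (SD). That score includes H2-Ab1, and a rise above WT was not tested. MHC class I genes were higher too (mean 0.77, 13 of 15; camera adjusted p = 0.00163, adjusted p = 0.476 with an estimated correlation), led by H2-Q7 (1.52 ± 0.34) and H2-Q6 (1.48 ± 0.41), near-identical copies whose reads can be shared.

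By camera 6 more lists were higher in Tie2Cre_H2Abf: basement membrane (mean 0.74, adjusted p = 0.00156), VEGF and angiopoietin signalling (1.15, 0.00465), Notch signalling (0.94, 0.00491), integrins and focal adhesion (0.72, 0.00742), proliferation (0.67, 0.0361) and endothelial identity (0.37, 0.0385). Sparc (1.06 ± 0.34), Vegfc (3.12 ± 1.08), Hey1 (1.69 ± 0.68) and Itgb3 (1.34 ± 0.49) are examples. The fibroblast list was lower (mean -1.09, 11 of 14; camera adjusted p = 0.0140), as was the ribosomal protein list (mean -0.44, 26 of 28; camera adjusted p = 0.0239). With an estimated correlation the adjusted p of these 8 lists lay between 0.450 and 0.697. Macrophage genes, lower at a mean of -0.58, did not pass (camera adjusted p = 0.0590).

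H2-Ab1 passed in every fit that left out 1 of the 7 libraries (highest adjusted p 0.0230). Fbln2 was lost without Tie2Cre_9502 or Tie2Cre_H2Abf_9582 (adjusted p up to 0.0811), and Fabp4 in all fits but that without Tie2Cre_H2Abf_9576 (adjusted p up to 0.336). Only the tip cell and interferon-gamma calls held in all 7 fits, the former at a mean of 0.96 without Tie2Cre_9501. With the olfactory share as a covariate, a setting chosen after the data were seen, 3 lists passed and 10 of the 12 calls ended; the tip cell (mean 1.01, camera adjusted p under 0.05) and interferon-gamma calls (mean 0.56, camera adjusted p = 0.00270) held. Without the satellite-rich Tie2Cre_9501, 4 lists passed: 9 of the 12 calls ended there, at adjusted p values of 0.111 for VEGF signalling and for MHC class I, 0.0569 for basement membrane and 0.366 for integrins, and also for Notch, MHC class II, proliferation, endothelial identity and fibroblast genes. Tie2Cre_H2Abf_9589 ended endothelial identity, MHC class II, proliferation and ribosomal proteins, Tie2Cre_9504 Notch and ribosomal proteins, Tie2Cre_9502 fibroblast and ribosomal proteins, Tie2Cre_H2Abf_9576 proliferation and Tie2Cre_H2Abf_9583 ribosomal proteins.

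Tie2Cre against WT compares 2 competent backgrounds. All Tie2Cre libraries carry numbers from another series than all WT libraries, and the labels do not say whether the series mark batches, so the background and the series cannot be told apart in this comparison. MHC class II genes were lower in Tie2Cre (mean -1.40, 8 of 8 members lower; camera adjusted p = 0.000714, adjusted p = 0.387 with an estimated correlation), with Cd74 at -1.98 ± 0.55 and H2-DMb1 at -2.14 ± 0.75, and 4 were lower adjusted over the list alone. Macrophage genes (mean -0.55, 15 of 18; adjusted p = 0.0143) and tip cell genes (mean -0.54, 14 of 18; adjusted p = 0.0184) were lower by camera, with Csf1r at -2.26 ± 0.74 and Dll4 at -0.99 ± 0.41. Ribosomal protein (mean 0.71, 28 of 28; adjusted p = 0.00650) and fibroblast genes (mean 1.24, 10 of 14; adjusted p = 0.0184) were higher by camera, with Mmp2 at 3.14 ± 0.89. With an estimated correlation these 4 lists stood at adjusted p = 0.736.

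In Tie2Cre against WT edgeR called 0 genes, with 1019 under an unadjusted p of 0.05, and DESeq2 called 78. Among genes eligible for naming, with a mean of at least 10 CPM, Trp53inp2 (2.77 ± 0.58) and Ttc17 (-3.08 ± 0.69) had the smallest p. No list call held in all 7 fits: Tie2Cre_9501 ended all but the ribosomal call, WT_9748 all but MHC class II, WT_9749 the tip cell, fibroblast and macrophage calls, WT_9772 the tip cell call, Tie2Cre_9502 the fibroblast call and Tie2Cre_9504 the ribosomal call. Without Tie2Cre_9501 or WT_9748 1 list passed, without WT_9771 12, and the MHC class II call stood at an adjusted p of 0.0980 without Tie2Cre_9501. The tip cell mean moved to as little as -0.01 (adjusted p = 0.875).

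CD4KO against the libraries labelled CD8KO compares a background classed as deficient with one classed as competent, without WT. A loss of Cd4 or Cd8a could not be seen in their RNA, so both labels are taken as given. The interferon-gamma response list was higher in CD4KO (mean 0.92, 27 of 29 members higher; camera adjusted p = 8.80e-11, adjusted p = 0.180 with an estimated correlation), with Gbp5 at 2.49 ± 0.52, Cxcl9 at 2.10 ± 0.57 and Gbp2 at 1.31 ± 0.41. MHC class II genes were higher (mean 1.23, 7 of 8; camera adjusted p = 0.000282, adjusted p = 0.180 with an estimated correlation), with Cd74 at 1.67 ± 0.56 and Ciita, the class II transactivator, at 3.23 ± 1.25. Macrophage genes were higher too (mean 0.83, 17 of 18; camera adjusted p = 0.000361, adjusted p = 0.964 with an estimated correlation), with the complement genes C1qc (1.68 ± 0.63) and C1qa (1.53 ± 0.62). Tip cell (mean -0.67, 15 of 18; adjusted p = 0.0309) and lymphatic endothelial genes (mean -1.28, 7 of 8; adjusted p = 0.0383) were lower by camera, at adjusted p = 0.964 and 0.271 with an estimated correlation. Adjusted over the list alone, 5 interferon-gamma genes were higher and 0 genes of the other four lists passed.

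For CD4KO against the libraries labelled CD8KO edgeR called 0 genes, with 845 under an unadjusted p of 0.05, and DESeq2 called 21. The interferon-gamma, MHC class II and macrophage calls held without each of the 6 libraries in turn. The tip cell call ended without CD4KO_9768 or CD8KO_9753 (adjusted p up to 0.343) and the lymphatic call without CD4KO_9769, CD4KO_9770 or CD8KO_9753 (adjusted p up to 0.296).

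The change from Tie2Cre to Tie2Cre_H2Abf was also tested against the change from WT to CD4KO, which shares no library with it. Fabp4 (-3.96 ± 0.68) and H2-Ab1 (-4.53 ± 0.78) differed, both lower in the former (edgeR adjusted p = 0.0321 each; 1073 genes under an unadjusted p of 0.05; 71 called by DESeq2, these included). By camera tip cell genes differed upwards (mean 1.62, 17 of 18; adjusted p = 2.67e-06), with Cxcr4 at 3.18 ± 0.94 and Dll4 at 1.96 ± 0.58, as did basement membrane genes (mean 0.67, 13 of 14; adjusted p = 0.0357). Fibroblast genes (mean -2.21, 12 of 14; adjusted p = 9.55e-05), with Fbln2 at -2.68 ± 0.57 and Mmp2 at -4.06 ± 1.21, and ribosomal protein genes (mean -1.12, 27 of 28; adjusted p = 3.81e-05) differed downwards. With an estimated correlation these 4 lists stood at adjusted p = 0.755, 0.776, 0.221 and 0.776 in that order. Both gene calls ended in 10 of the 14 fits without 1 library (adjusted p up to 0.131 for Fabp4 and 0.127 for H2-Ab1). Without 1 library the tip cell and fibroblast calls always held, the ribosomal call ended without CD4KO_9768 (mean -0.69, adjusted p = 0.0532) and the basement membrane call ended in 8 fits (adjusted p up to 0.398).

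**Figure D3:**
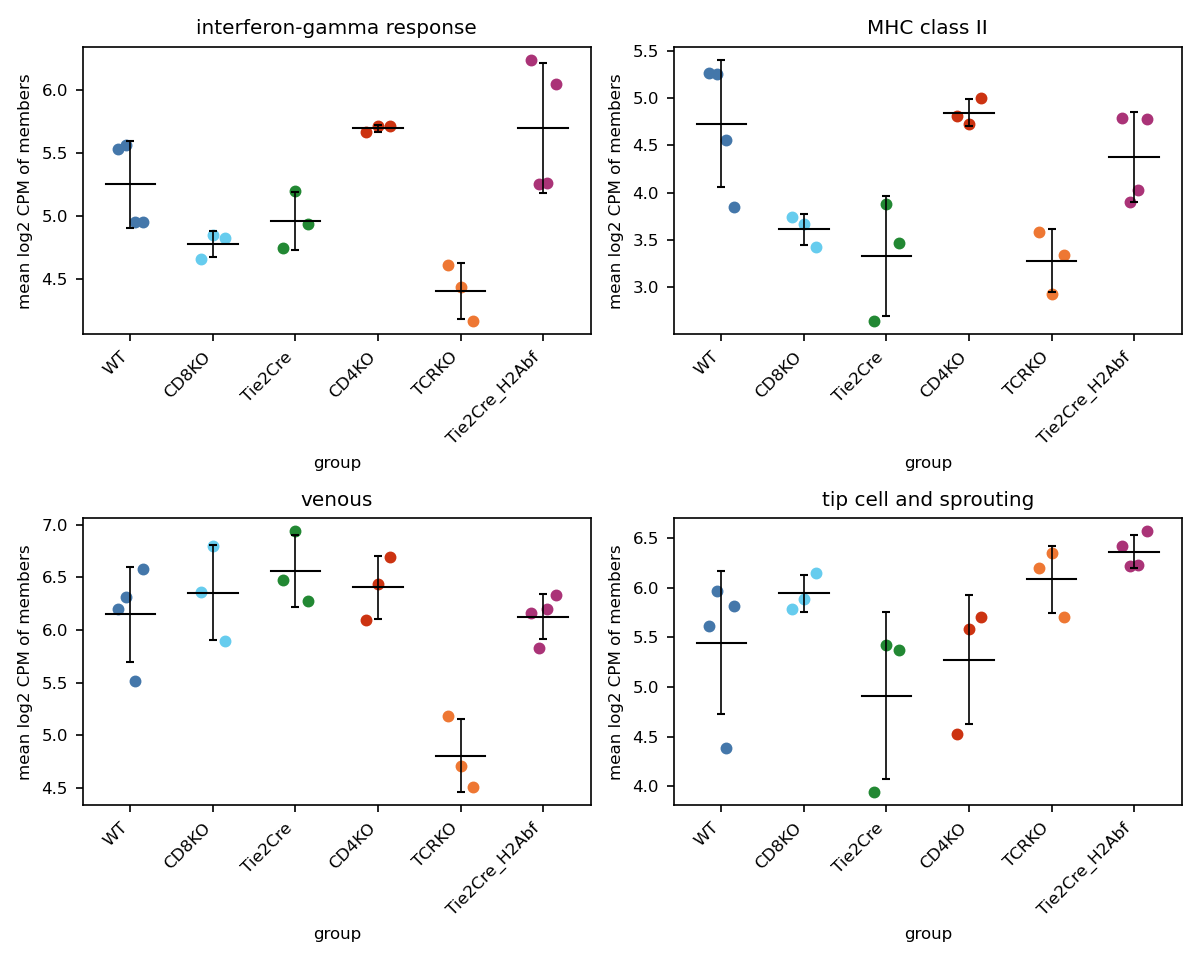
Mean log2 CPM of the tested members of 4 gene lists (vertical axes) by background, 1 point per library, with the group mean and SD. The venous score was 4.81 ± 0.35 in TCRKO and 6.15 ± 0.45 in WT, and the interferon-gamma score was 5.70 ± 0.52 in Tie2Cre_H2Abf and 4.96 ± 0.23 in Tie2Cre.

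Cell types other than endothelium were read from marker lists. In the fibroblast list the mean log2 CPM was 0.18 ± 1.05 in WT (SD, n = 4) and 1.42 ± 0.64 in Tie2Cre (SD, n = 3), against 7.19 ± 0.70 and 7.50 ± 0.41 for the endothelial identity list. The macrophage list had a mean of 4.33 ± 0.64 in WT and 3.20 ± 1.25 in Tie2Cre_H2Abf. The lists for B cells, NK cells, adipocytes, epithelial and tumour cells, erythroid cells and neutrophils had fewer than 5 tested genes each and were not tested. The NK cell list held 1 tested gene, Klrk1, at 5.93 ± 5.07 CPM in WT (SD, n = 4) and at most 1.25 CPM in the other 16 libraries. The 4 comparisons made against WT share its 4 libraries, so their common features, such as the higher ribosomal protein genes, are not independent of each other. The difference of effects and the comparison by CD4 status use these libraries too. The WT libraries also had the fewest genes with at least 5 counts, 9552 to 10239, against 10698 or more in each of the other 16 libraries.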

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

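All tests in this part were chosen only after the result was seen, except the test of keratin-associated, taste receptor and defensin genes and the difference of the Tie2Cre_H2Abf and CD4KO effects. Rules for reading the tests of a shared response were tightened after a first look at their values. The bound for the tests with a covariate for the interferon-gamma list was changed more than once after their values were seen, and both bounds are given below.

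In 17 of 104 checks a value stood far from the others. Each check took 1 measure in WT, in Tie2Cre_H2Abf or in all libraries of 1 CD4 class. A rate of 1 in 20 would give 5.2, but it assumes independent, normally distributed values. The checks overlap and many measures are skewed, so that rate is a rough guide only. WT_9771 had a satellite share of 45.9%, against 0.963% for the nearest WT library and 19.3% for the nearest competent one. It also had a Pecam1 level of 435 CPM (nearest 1078) and an endothelial identity score of 6.14 (nearest 7.46 in WT and 7.07 among competent libraries). Tie2Cre_9501 had 5826 CPM of olfactory receptor counts among protein-coding counts (nearest 2766, in WT_9771). Protein-coding counts include satellite-like genes, so the order of these 2 satellite-rich libraries is uncertain. Tie2Cre_H2Abf_9583 had a satellite share of 2.03% (nearest 0.0791%), 615 CPM of olfactory receptor counts (nearest 139), 18777 detected genes (nearest 14159) and 3.74 CPM of Cd4 (nearest 0). CD4KO_9768 had 15.7 CPM of Cd4 (nearest 7.55) and low scores for Notch signalling (3.51, nearest 4.21), proliferation (1.28, nearest 2.14) and tip cells (4.53, nearest 5.59). Tie2Cre_H2Abf_9582 had a low leukocyte adhesion score (3.50, nearest 4.09). Protein-coding counts were 3.54 M (mega) in CD4KO_9770 (nearest 1.90 M) and 5.16 M in CD8KO_9752 (nearest 1.97 M).

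The effect of Tie2Cre_H2Abf over Tie2Cre differed from that of CD4KO over WT for Fabp4 (-3.96) and H2-Ab1 (-4.53), and by camera for tip cell (1.62), basement membrane (0.67), ribosomal protein (-1.12) and fibroblast genes (-2.21). It differed from that of TCRKO over WT for the interferon-gamma response (1.58; exact permutation p = 0.00490, adjusted p = 0.0294 over 12 tests, 1225 splits) and for MHC class II (2.49; exact permutation p = 0.00327, adjusted p = 0.0294). The 2 reference backgrounds differ as well, with MHC class II lower in Tie2Cre than in WT (mean -1.40), so part of the MHC class II difference may lie in the references. The other 10 of these tests did not pass (smallest adjusted p 0.0710 by exact permutation), and tip cell and fibroblast genes, called by camera for the difference from CD4KO, stood at 0.153 and 0.0710 there.

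Cd8a RNA was present in the 3 libraries labelled CD8KO. T cells in the sort are argued against: 7 T cell genes together reached at most 2.30% of the Cd8a count (21 counts). Dendritic cells, some of which carry CD8 alpha, are argued against too, as Xcr1, Clec9a, Flt3 and Batf3 together reached at most 8.64% (79 counts). A transcript of the altered allele could account for the lowest level of 39.0 CPM, but the tables hold no read positions, so it stays open, as does an exchange of labels with samples outside the series, which was not tested and would change what every comparison with these libraries compares. No biological explanation was tested.

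Satellite and olfactory receptor counts were high in some libraries of several backgrounds. Genomic DNA may be their source: over 20 libraries the olfactory share went with that of 140 other silent genes (keratin-associated, taste receptor and defensin; Spearman rho 0.832, Pearson r 0.920, permutation p = 1e-05 for both, the smallest they can give; r 0.896 without Tie2Cre_9501 and WT_9771). Both shares have protein-coding counts as divisor, so part of this correlation is built in, and how much was not tested. The olfactory share fell as protein-coding counts rose (rho -0.701, permutation p = 0.000840, r -0.66, permutation p = 0.00111, and r -0.53 without the same pair). Protein-coding counts are the divisor of that share, so a fall is built in. Whether a low yield of coding RNA contributes therefore cannot be decided from it. With the satellite share the olfactory share had rho 0.899 and r 0.935 (permutation p = 1e-05; r 0.910 without the pair). Mouse background stays open (24.5% of the variance between backgrounds; permutation p = 0.498).

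The interferon-gamma response list was lower in TCRKO than in WT and higher in Tie2Cre_H2Abf than in Tie2Cre. For both the tables argue against macrophage RNA and against genomic DNA as the whole cause: in TCRKO the mean with the macrophage score as covariate was -0.87 (camera adjusted p = 5.83e-08) and with the olfactory share -0.89 (camera adjusted p = 1.25e-08), against -0.84 without. In Tie2Cre_H2Abf the means were 0.66 (SE 0.25; camera adjusted p = 0.000783) and 0.56 (SE 0.22; camera adjusted p = 0.00270), against 0.74 without; they lie 2.66 and 2.52 SE from 0 but only 1.92 and 1.69 SE from 0.25 of the mean without, so a cause of part of the change stays open. A biological difference between backgrounds is among the open explanations for both, and the calls themselves end with an estimated correlation (adjusted p = 0.188 and 0.450). The olfactory share is understated in the satellite-rich WT_9771 and Tie2Cre_9501, so as a covariate it is a rough measure of genomic DNA.

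Other splits of the same libraries were counted for each number of calls. For the genes called in Tie2Cre_H2Abf against Tie2Cre the real split called 3, and the highest of the other splits called 1. Only the real one of 35 splits gave as many (1 of 35), the smallest share these splits can give. This is 1 of 16 such counts, read without adjustment, and 1 of the 3 genes is H2-Ab1, which the allele removes by design. Chance is therefore not excluded for this count. Where the real count of genes is 0 every split gives as many by construction, so the share tests nothing; the highest of the other splits was 945 by CD4 status (100 of 100 splits), 31 in CD4KO against WT (35 of 35), 2 in CD8KO against WT (35 of 35) and 88 in Tie2Cre against WT (35 of 35). Nor can chance be excluded for the other counts with enough splits. For genes the real value and the highest other were 4 and 12 in TCRKO against WT (2 of 35) and 2 and 5 for the difference of effects (5 of 100). For lists they were 2 and 19 by CD4 status (73 of 100), 2 and 12 in CD4KO (26 of 35), 6 and 19 in TCRKO (11 of 35), 6 and 15 in CD8KO (16 of 35), 12 and 16 in Tie2Cre_H2Abf (10 of 35), 5 and 16 in Tie2Cre (13 of 35) and 4 and 17 for the difference (54 of 100). For CD4KO against CD8KO the 10 splits are too few for a share under 0.05, with 0 genes and at most 0 in another split (10 of 10), and 5 lists and at most 6 (2 of 10). Genes under an unadjusted p of 0.05 were counted over the same splits, the real one included. At least the real number came in 32 of 35 splits for CD4KO, 19 of 35 for TCRKO, 10 of 35 for CD8KO and 21 of 35 for Tie2Cre, each against WT. It came in 2 of 35 for Tie2Cre_H2Abf against Tie2Cre, 21 of 100 by CD4 status, 54 of 100 for the difference and 2 of 10 for CD4KO against CD8KO. Splits that called 945, 88 or 31 genes where the real one called 0 point to a structure of the samples other than the groups. The split with 88 put Tie2Cre_9501, Tie2Cre_9504 and WT_9771 together, and that with 31 put CD4KO_9768, WT_9771 and WT_9772 together. In each case these libraries had the largest olfactory receptor shares of their comparison. Whether that share is the cause was not tested.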

How the results depend on the processing

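The tests without the 2 satellite-rich libraries, with abundant RNA and satellite genes removed and with the olfactory share as a covariate were chosen only after the result was seen; the others were planned.

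Counts of genes past the threshold, in the order CD4 status, CD4KO, TCRKO and CD8KO against WT, Tie2Cre_H2Abf against Tie2Cre, Tie2Cre against WT, CD4KO against CD8KO and the difference of effects, were 0, 0, 4, 0, 3, 0, 0 and 2. Under DESeq2 they were 11, 94, 177, 82, 57, 78, 21 and 71, including 4 of 4, 3 of 3 and 2 of 2 of the called genes; limma-voom called 5 for TCRKO, with 1 of the 4 among them. Without a filter the counts were 10 for CD4KO, 31 for TCRKO, 12 for CD8KO, 9 for Tie2Cre_H2Abf, 2 for CD4KO against CD8KO and 31 for the difference. With limma-voom they were 8 by CD4 status, 1 for CD8KO, 15 for Tie2Cre_H2Abf and 4 for the difference, and with the 6-group model 4 by CD4 status. RLE factors gave 9 for TCRKO, 5 for Tie2Cre_H2Abf and 4 for the difference. A filter of 5 CPM in 10 libraries gave 15, 10 and 6 for the same comparisons. Effective-length offsets gave 2 for TCRKO and 0 for the difference. The nearest WT library numbers gave 0 for TCRKO and 3 for CD8KO, and a fit of only the 2 groups gave 0 for TCRKO and 1 for Tie2Cre_H2Abf. Without the satellite-rich libraries TCRKO had 15. With the olfactory covariate TCRKO had 8, CD8KO 2 and the difference 5. The cause of these moves was not tested.

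Lists past the threshold were 2, 2, 6, 6, 12, 5, 5 and 4 in the same order. With an estimated correlation they were 0 in all 8, and by fry 0 in all but TCRKO (4). Without a filter they were 14 by CD4 status, 6 for CD4KO, 10 for TCRKO and 16 for CD8KO. Without the satellite-rich libraries they were 1 by CD4 status, 1 for CD4KO, 14 for TCRKO and 6 for Tie2Cre_H2Abf. With the olfactory covariate they were 3 for Tie2Cre_H2Abf and 2 for Tie2Cre against WT. Removing abundant RNA and satellite genes left all 16 counts within 1.5 times.

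Leaving out 1 library gave 0 to 1 genes by CD4 status, 0 to 1 for CD4KO, 0 to 18 for TCRKO, 0 to 1 for CD8KO, 1 to 3 for Tie2Cre_H2Abf, 0 to 1 for Tie2Cre against WT, 0 to 0 for CD4KO against CD8KO and 0 to 4 for the difference. Lists ran from 1 to 8, 0 to 2, 5 to 14, 1 to 12, 4 to 13, 1 to 12, 4 to 6 and 2 to 8. The counts of 1 gene came without CD4KO_9770 by CD4 status, without WT_9772 for CD4KO and CD8KO, and without Tie2Cre_9502 for Tie2Cre against WT; by CD4 status 8 lists came without CD8KO_9753 and 1 without CD8KO_9751, Tie2Cre_9501 or WT_9771. The ribosomal protein list of Tie2Cre_H2Abf turned its camera direction without Tie2Cre_9504, at a mean of -0.10 (adjusted p = 0.919), against -0.63 without Tie2Cre_H2Abf_9582; the cause was not tested.

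Of the values of named genes without 1 library, 2378 kept their side of the threshold, 47 lost and 14 gained a call; under other settings 2596 kept it, 20 lost and 173 gained one. Of list values without 1 library 262 kept it and 80 lost the call, and under other settings 139 and 113. DESeq2 gave no adjusted p for 8 values of named genes. RLE factors moved the median of all genes by at most -0.16 (Tie2Cre_H2Abf against Tie2Cre). Of the 42 list calls 1 ended under another scaling, endothelial identity in Tie2Cre_H2Abf (adjusted p = 0.106 with RLE, mean 0.38 relative to that median).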

Other observations

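The tests of a shared response were planned before their result was seen, but the rule for reading them was tightened after a first look at their values. The genes in the next paragraph were picked only after their values were seen, with no test of their own.

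Trp53inp2, an autophagy regulator, stood at 2.65, 6.58, 0 and 2.27 CPM in the 4 WT libraries and between 14.7 and 33.6 CPM in the other 16. Klrk1, which encodes the NKG2D receptor of NK and T cells, went the other way, at 3.64, 0.850, 6.57 and 12.7 CPM in WT and at most 1.25 CPM elsewhere. The WT values of Trp53inp2 lay below all others; those of Klrk1 overlapped with other backgrounds, as 1 WT library stood below 1.25 CPM. Pfkfb3, a glycolysis regulator of the hypoxia list, had a value of 1.83 ± 0.50 in Tie2Cre_H2Abf against Tie2Cre and of 2.09 ± 0.52 in CD4KO against the libraries labelled CD8KO (edgeR adjusted p = 0.576 and 0.833; 0.0219 and 0.00943 adjusted over the list alone).

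Group levels of 3 genes are set side by side here, picked after their values were seen and without a test. Other matrix genes went the other way, such as Col6a2, which was higher in TCRKO, CD4KO and the libraries labelled CD8KO than in WT. Fbln2 stood at 63.7 ± 11.6 CPM in TCRKO (SD, n = 3), 78.7 ± 22.8 in Tie2Cre_H2Abf (SD, n = 4) and 247 ± 141 in CD4KO (SD, n = 3). Fbn1 stood at 1.38 ± 0.787, 5.78 ± 2.37 and 23.3 ± 20.9 CPM in the same order. Fabp4 stood at 38.9 ± 11.6, 28.8 ± 14.5 and 137 ± 65.7 CPM. The levels of the competent backgrounds are not set beside these, so a change against them cannot be read from these values.

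A shared response of deficient backgrounds was a hypothesis. Over 4201 genes, which are not independent replicates, the changes of Tie2Cre_H2Abf over Tie2Cre and CD4KO over WT, which share no library, had a correlation of r -0.00436 (Spearman rho -0.0204, one-sided exact permutation p = 0.522, 1225 splits, 95th percentile 0.170). For Tie2Cre_H2Abf and TCRKO it was r 0.0940 (rho 0.0541, one-sided exact permutation p = 0.201, 95th percentile 0.182). Neither lay above the 95th percentile of the values of permuted labels. The first met the planned bound against a shared response, the permuted median, by less than the spread of the permuted values. Under the rule tightened after a first look, neither lay far enough below to exclude a shared response, which therefore may or may not exist.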
